A study of Rattus norvegicus with 9 samples.

How the data were processed

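Posterior cricoarytenoid muscle of rats aged 6, 18 and 30 months was measured on 9 Affymetrix Rat Genome U34 arrays, 3 per age, each hybridized with RNA pooled from 4 animals. Per the labels' protocols, the authors hybridized biotinylated cRNA and stained it with a streptavidin-bound dye. The arrays were therefore treated as having 1 channel, although a label field names a pair of dyes. The deposited values are signal intensity from Affymetrix Microarray Suite 5.0 (MAS 5.0), which the authors computed and left on a linear scale. Per the submitters' processing notes, they kept genes with the same detection call in all replicates, required difference calls to match in all pairs of arrays, and asked for an average change over 1.7. Those calls were not used here. As an alternative, a fold rule on signals alone asked for a ratio of mean signals over 1.7 and no overlap between ages. The build of the arrays' genome reference and the exact software release are not given in the sources used here.

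The table held 8799 probe sets, of which 59 controls were left out. It had 0 missing values and 0 values at or under 0, with a lowest signal of 0.1 and a highest of 48487.6. The 2% trimmed mean was 500.868 to 500.968 over the arrays, so the authors' global scaling was kept. Signals were analysed as log2(signal + 32). Probe sets in the upper 60% by mean log2 over all arrays were tested, a cutoff of 6.60, which left 5244 of 8740. Gene names came from the platform's annotation table, where 7006 probe sets carry 1 symbol, 308 several and 1426 none. A reference table of the rat assembly GRCr8 was used for names only: 6994 gene IDs matched and 0 symbols changed. Of the tested probe sets 4341 carried 1 symbol, 222 several and 681 none, for 3163 genes. Where a gene had several probe sets, the one with the highest mean represented it in lists.

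A linear model with 1 mean per age was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes), with 6 residual and 3.69 prior degrees of freedom. The contrasts were 18 against 6, 30 against 6 and 30 against 18 months, plus an F-test for any difference among ages. P-values were two-sided and adjusted by Benjamini and Hochberg over 5244 probe sets at a threshold of 0.05. They measure the spread between pools of animals, not between animals. An exact permutation test of 3 against 3 arrays cannot go below p = 0.1, so none was used for single probe sets. Splits of the arrays were used only to compare numbers of calls. Errors of log2 changes are standard errors from limma, and errors of signals are standard deviations over 3 arrays.

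Samples were grouped by the age in the labels. The contrasts, the threshold, the gene lists and the rule for naming genes were fixed before the data were examined. The rule named, per comparison and direction, up to 12 genes past the threshold without overlap between ages, by size of change, each by its probe set with the highest mean. Where fewer than 10 genes passed, the names were filled by p from genes without overlap and with a ratio of mean signals over 1.7, given as values without a call. From each list it named up to 4 genes past the threshold, or else the 2 with the highest signal. Genes past the threshold only adjusted over the list alone, single examples from lists and a few others were named after their values were seen.

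There were 30 gene lists with 734 genes, written from general knowledge. They covered fibre types, junction, energy metabolism, matrix, stress, immune genes, growth, and markers of other cell types. Coverage was partial: 21 of 26 collagen and matrix genes were tested, 28 of 47 respiratory chain genes, 36 of 77 ribosomal genes and 15 of 23 antigen-presentation genes. Lists with at least 4 genes past the signal filter were tested, which left 1 out, cartilage. Camera of limma compared each list with all other genes at a preset correlation of 0.01 and, as an alternative, with an estimated correlation. Fry was the other list test, and it asks whether a list's genes move one way without comparison with other genes. List p-values were adjusted over 29 lists per comparison.

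The scripts were tested on simulated data shaped like the comparison of 30 with 6 months, with 5244 probe sets. Changes of 1.5-fold were recovered in 50% of 50 probe sets, of 2-fold in 98%, and of 3- and 4-fold in 100% each, with 7 false calls; 0 calls were made in the comparison without a simulated change. A simulated list shift of -0.4 was recovered among 29 lists and 3163 genes, with 0 other lists called. The simulated values varied independently between genes, whereas the estimated correlation in the data reached 0.46, in the fast-fibre list. The simulation therefore does not show how often camera calls unshifted lists of correlated genes. Its many large changes also make the adjusted threshold easier to pass than the few calls in the data do. The recovered shares are therefore not the power in the data. At 18 months, for example, *Col3a1* had a log2 change of -1.20 without passing (limma adjusted p = 0.167).

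Alternatives changed one choice at a time. They were a smaller pseudocount of 8 or one 4 times the main one, no filter or the upper 40%, quantile normalization, median centring, each array left out in turn, and replicate number as a block. Further ones were eBayes with an intensity trend and robust settings, estimated array weights, only the ages compared, a threshold of 0.10, the fold rule, probe sets averaged per gene, camera with an estimated correlation, and fry. A pair of fits without certain arrays was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.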

Results

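The posterior cricoarytenoid, the muscle that opens the vocal folds, was profiled in rats aged 6, 18 and 30 months. Each age was measured on 3 oligonucleotide arrays, and each array carried RNA pooled from 4 animals, so the spread between arrays of an age is a spread between pools of animals. The series asks how gene expression in this laryngeal muscle shifts with age and uses 6 months as the baseline. The 2% trimmed mean signal was 500.9 on every array to within 0.1. Median signals were 122, 125 and 120.1 at 6 months, 116, 104 and 116 at 18 months, and 111, 105 and 112 at 30 months. The 100 strongest probe sets carried 27.6% to 32.9% of the summed signal. The ratio of 3' to 5' probe sets was 1.03 to 1.17 for *Gapdh* and 0.904 to 1.17 for β-actin. Log2 signals of arrays of the same age correlated at 0.972 to 0.984 over 9 pairs, and those of different ages at 0.967 to 0.988 over 27 pairs. These correlations are across probe sets, which are not independent replicates. With 3 arrays per age, the number of arrays limits the precision.

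The first comparison asked what had shifted by 18 months. *Rab3b*, which encodes a small GTPase of regulated secretory vesicles, rose from a mean signal of 1128 ± 112 to 2431 ± 83.3 (SD, n = 3 arrays per age). That is 2.15-fold, or 1.09 on the log2 scale with a standard error of 0.12 (adjusted p = 0.0132), and its other probe set also passed the threshold. *Col1a2*, which encodes the α2 chain of type I collagen, fell from 1216 ± 141 to 546 ± 65.4 (SD, n = 3), 2.23-fold (log2 change -1.11, SE 0.13, adjusted p = 0.0168). The fourth of the 4 probe sets past an adjusted p of 0.05, U75405UTR#1_f_at, carries no gene symbol in the annotation table and fell by 1.14. In total 5244 probe sets were tested, and 2 rose and 2 fell. At an unadjusted p under 0.05 there were 452, of which 157 were higher and 295 lower, against 262.2 expected by chance. The median log2 change over all probe sets was -0.04, and -0.0035 after quantile normalization, so the scaling may account for part of the excess of lower ones. In 717 probe sets (13.7%) the values of both ages did not overlap, against 10% expected by chance. The limma count was 0 without replicate 2 of 6 months and without replicate 3 of 18 months, where 407 and 440 probe sets had an unadjusted p under 0.05. It was 2 without replicate 1 of 6 months and 2 without replicate 2 of 18 months, where 1 of these was among the 4. *Rab3b* and *Col1a2* each passed in 5 of the 9 fits that left out 1 array, and in 2 of the 6 fits that left out an array of either compared age.

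Other genes led the ranking at 18 months without passing the threshold. The collagen genes *Col1a1* (log2 change -1.07, adjusted p = 0.122), *Col5a2* (-0.88) and *Col3a1* (-1.20) lay on the side of *Col1a2*. *Rin1*, which encodes an effector of Ras and Rab5, read 39.2 ± 13.4 at 6 months and 127 ± 14.5 at 18 months (SD, n = 3, log2 change 1.18, adjusted p = 0.0513). *Irf7*, an interferon-response transcription factor, had a log2 change of 0.77 (adjusted p = 0.122), and *Ptpn23* one of 0.88. The glutathione peroxidase *Gpx2* (0.64), the channel subunits *Abcc8* (0.65) and *Kcnj1* (0.77), the vitamin D hydroxylase *Cyp24a1* (0.76) and the clock gene *Per2* (0.71) also ranked among the higher genes. So did *Ppil2* (0.67), *Arhgap25* (0.67) and *Vps39* (0.52). Among the lower genes were the activin subunit *Inhba* (-0.95), the transferrin receptor *Tfrc* (-0.95), the coagulation factor subunit *F13a1* (-0.80), *Kcnh8* (-0.63) and *Cnga1* (-0.60). The RNA editing enzyme *Adar* read 90.0 at 6 months, 28.9 at 18 months and 102 at 30 months. *Anp32a* (545, 203 and 565) and the NADPH oxidase subunit *Cyba* (396, 173 and 362) had the same course in the probe set with the highest signal, and none of the 3 passed the threshold in any comparison. The other *Anp32a* probe set had a log2 change of 0.29 at 18 months and of -0.02 from 18 to 30 months. The other probe sets of *Kcnj1* and *Ptpn23* lay on the lower side at 18 months, at -0.44 and -0.24.

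Gene lists fixed beforehand were compared with all other genes by camera, which called 6 of 29 lists at 18 months, 5 higher and 1 lower. The collagen and matrix list was lower as a group: 19 of its 21 measured genes lay below 6 months, with a median log2 change of -0.31 (adjusted p = 2.7e-08; adjusted p = 0.410 with an estimated correlation). In it 1 gene passed over all genes, *Col1a2*, and 5 passed adjusted over the list alone. Genes that passed only so are named here and in the other lists after their values were seen, and in this list they are *Col1a1*, *Col5a2*, *Col3a1* and *Fn1* (-0.72). The fibronectin gene *Fn1* read 1119 ± 232 at 6 months and 660.0 ± 102 at 18 months (SD, n = 3). Its other tested probe sets, of weaker signal, had log2 changes of only -0.03 and -0.16.

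The fast-fibre list, which holds sarcomere and calcium-handling genes, had a median of 0.18 (adjusted p = 4.0e-05; adjusted p = 0.432 with an estimated correlation), and 12 of 14 genes were higher, but after quantile normalization the median was 0.00. In it 2 genes passed adjusted over the list alone and 0 over all genes. The myosin heavy chain gene *Myh2* read 9443 ± 283 at 6 months and 13485 ± 731 at 18 months (SD, n = 3, log2 0.51, SE 0.11), and the calcium pump gene *Atp2a1* had a log2 change of 0.40. The slow-fibre list had a median of 0.23, with 8 of 10 genes higher (adjusted p = 0.00963; adjusted p = 0.432 with an estimated correlation). Again 2 genes passed adjusted over the list alone and 0 over all genes, the slow myosin heavy chain gene *Myh7* (0.72, SE 0.17) and the light chain gene *Myl2* (0.64, SE 0.15). In the respiratory chain list 25 of 28 genes were higher with a median of 0.09 (adjusted p = 0.00314; adjusted p = 0.432 with an estimated correlation), and under quantile normalization the direction of the test turned, with a median of 0.0017. The creatine list had a median of 0.15 with 7 of 8 genes higher (adjusted p = 0.0103; adjusted p = 0.410 with an estimated correlation). Muscle creatine kinase, *Ckm*, read 34163 at 6 months and 44700.5 at 18 months; it was the 1 gene to pass adjusted over the list alone, and 0 passed over all genes. The fatty acid oxidation list had 20 of 26 genes higher, a median of 0.09 (adjusted p = 0.0103; adjusted p = 0.432 with an estimated correlation) and 0 genes past either adjustment. After quantile normalization camera called 1 list, the collagen list.

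The median log2 change over all probe sets depended on signal strength, which bears on these lists of strongly expressed genes. At 18 months it ran from -0.12 in the weakest of 5 equal groups of probe sets to 0.04 in the strongest, and at 30 months from -0.15 to 0.04. Without replicate 3 of 18 months camera called 2 lists at that age, and the slow-fibre, respiratory chain, creatine and fatty acid lists were then not called, with adjusted p of 0.0916, 0.0916, 0.0574 and 0.0571. The slow-fibre call was also lost without replicate 3 of 6 months (adjusted p = 0.125). In each of these fits the slow-fibre median was 0.14, against 0.23 in the main fit. The call of the fatty acid list was lost without replicate 1 or 2 of 6 months or replicate 2 of 18 months (adjusted p = 0.0783, 0.0516 and 0.0788). Its medians there were 0.05, 0.05 and 0.09, against 0.09 in the main fit. By fry, which asks whether a list's genes move one way on balance, 1 list passed at 18 months, the creatine list (adjusted p = 0.00337).

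**Figure D1:**
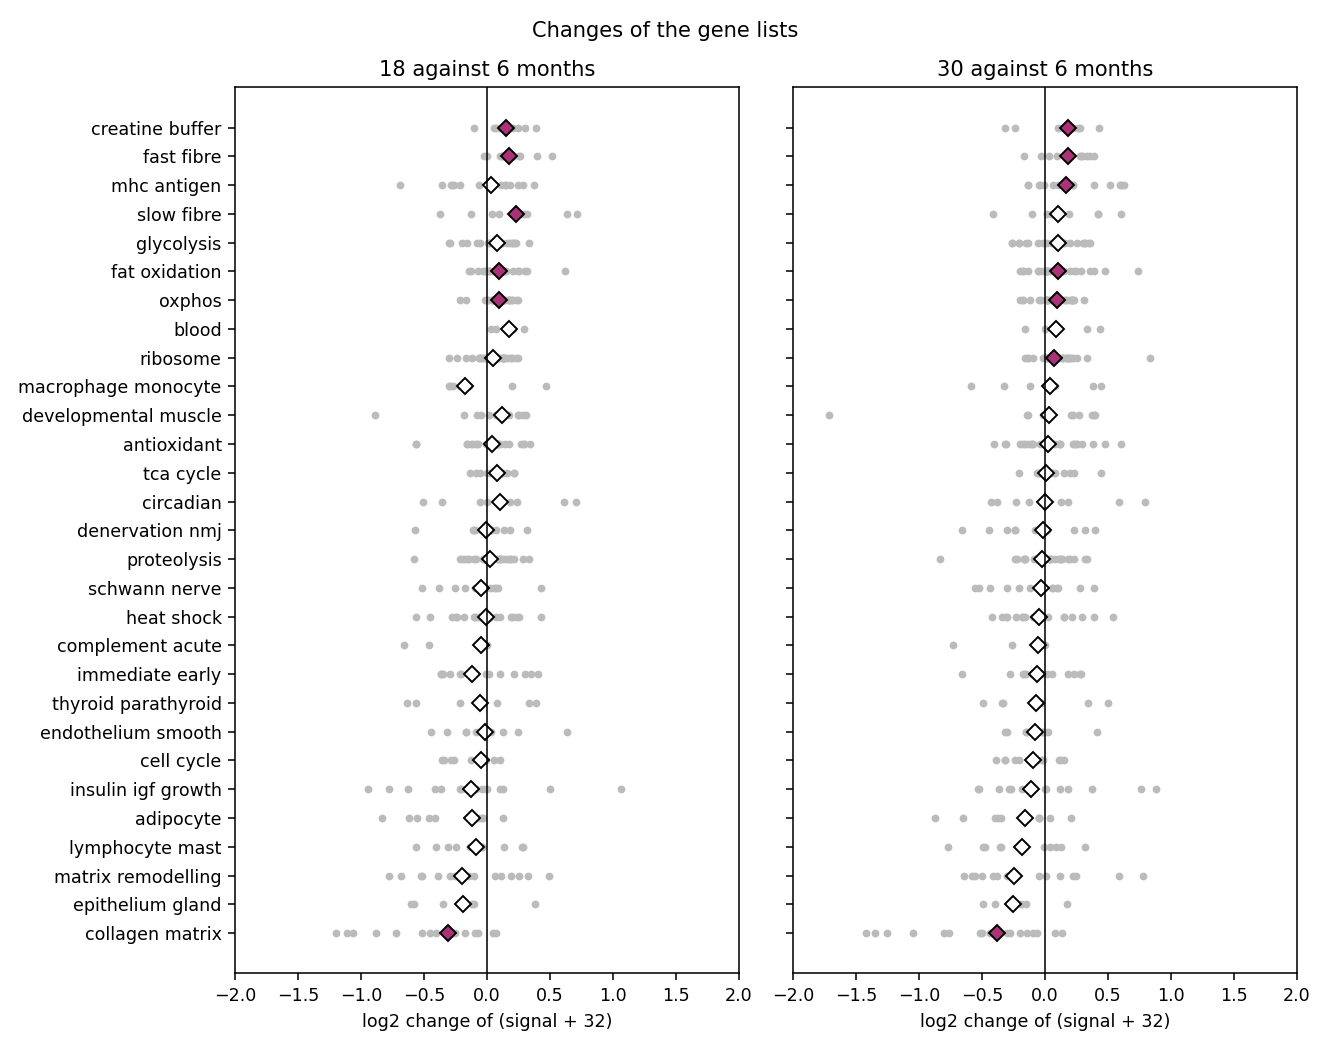
Log2 change of signal + 32 against 6 months at 18 months (left) and 30 months (right) for each of 29 gene lists, with grey dots for genes, a diamond at the list's median, and a filled diamond where camera called the list. The collagen list lay lowest in both panels, and the filled lists on the higher side had medians of at most 0.23; the respiratory chain list turned direction under quantile normalization.

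The comparison of 30 with 6 months asked what separated the oldest muscle from the baseline, and 4 fibrillar collagen genes were lower. *Col1a2* fell 2.66-fold, from 1216 ± 141 to 457 ± 34.8 (SD, n = 3 arrays per age; log2 change -1.35, SE 0.13, adjusted p = 0.00920). *Col1a1* fell 2.42-fold, from 2898 ± 429.5 to 1197 ± 189 (log2 change -1.25, SE 0.18, adjusted p = 0.0252), and *Col3a1*, the type III chain, fell 2.75-fold, from 2766 ± 705 to 1004 ± 204 (log2 change -1.42, SE 0.23, adjusted p = 0.0418). *Col5a2*, a type V chain that takes part in fibril assembly, fell 2.25-fold to 216 ± 21.2 (log2 change -1.05, SE 0.17, adjusted p = 0.0389). *Pip4p1*, which encodes a lysosomal phosphoinositide phosphatase, fell 2.24-fold, from 1048 ± 50.1 to 468 ± 53.3 (log2 change -1.12, adjusted p = 0.0237).

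Among the genes named by the rule, 5 rose at 30 months. *Rab3b* rose 2.12-fold to 2395 ± 234 (SD, n = 3; SE 0.12 on the log2 scale, adjusted p = 0.0131), and *Rin1* to 119 ± 22.1 (1.09, SE 0.17, adjusted p = 0.0336). *Ptpn23*, an endosomal sorting phosphatase gene, rose from 94.5 ± 20.9 to 306 ± 39.8 (SD, n = 3; 1.42, SE 0.20, adjusted p = 0.0237), though its other probe set had a log2 change of -0.08. *Irf7* rose from 91.9 ± 15.2 to 225 ± 21.9 (SE 0.14, adjusted p = 0.0184), with 0.49 in its other probe set. *Stk39*, a kinase of ion transport, rose from 285 ± 20.8 to 611 ± 34.8 (1.02, SE 0.14, adjusted p = 0.0206), with 0.03 and -0.66 in its other probe sets. A further 3 genes passed through probe sets that do not represent the gene in the lists, and were named after their values were seen: *Pacs1* (-0.89), *Dock8* (-1.15) and *Cd74* (0.83, probe set X14254cds_at).

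Over 5244 probe sets, 17 passed at 30 months, 8 higher and 9 lower, in 13 named genes; 2 carried no gene symbol. At an unadjusted p under 0.05 there were 677, with 219 higher and 458 lower. The median log2 change over all probe sets was -0.05, and -0.01 after quantile normalization. Part of the excess of lower ones may therefore come from the scaling. In 1166 probe sets (22.2%) both ages did not overlap, against 10% by chance. The limma count was 0 without replicate 2 of 6 months, replicate 2 of 30 months or replicate 3 of 30 months, where 580.0, 416 and 588 had an unadjusted p under 0.05. It was 3 and 2 without replicates 1 and 3 of 6 months, and 10 without replicate 1 of 30 months, of which 8 were among the 17. Of the 6 fits that left out an array of either compared age, *Col1a2* passed in 3, *Rab3b* in 2, *Stk39* and *Col1a1* in 1 each, and *Col3a1*, *Col5a2*, *Ptpn23*, *Irf7*, *Pip4p1* and *Rin1* in 0. Over all alternatives *Rin1* lost its call in 16 of 21, *Col5a2* in 15 of 22 and *Col3a1* in 14 of 22. The calls of *Col5a2* and *Col3a1* ended with a pseudocount of 8, without filtering and after quantile normalization, and that of *Rin1* without filtering and with the larger pseudocount. Replicate numbers paired the arrays in part, and with replicate number as a block the calls of *Col1a1* and *Col5a2* (both adjusted p = 0.0521) and *Rin1* (adjusted p = 0.0611) ended.

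**Figure D2:**
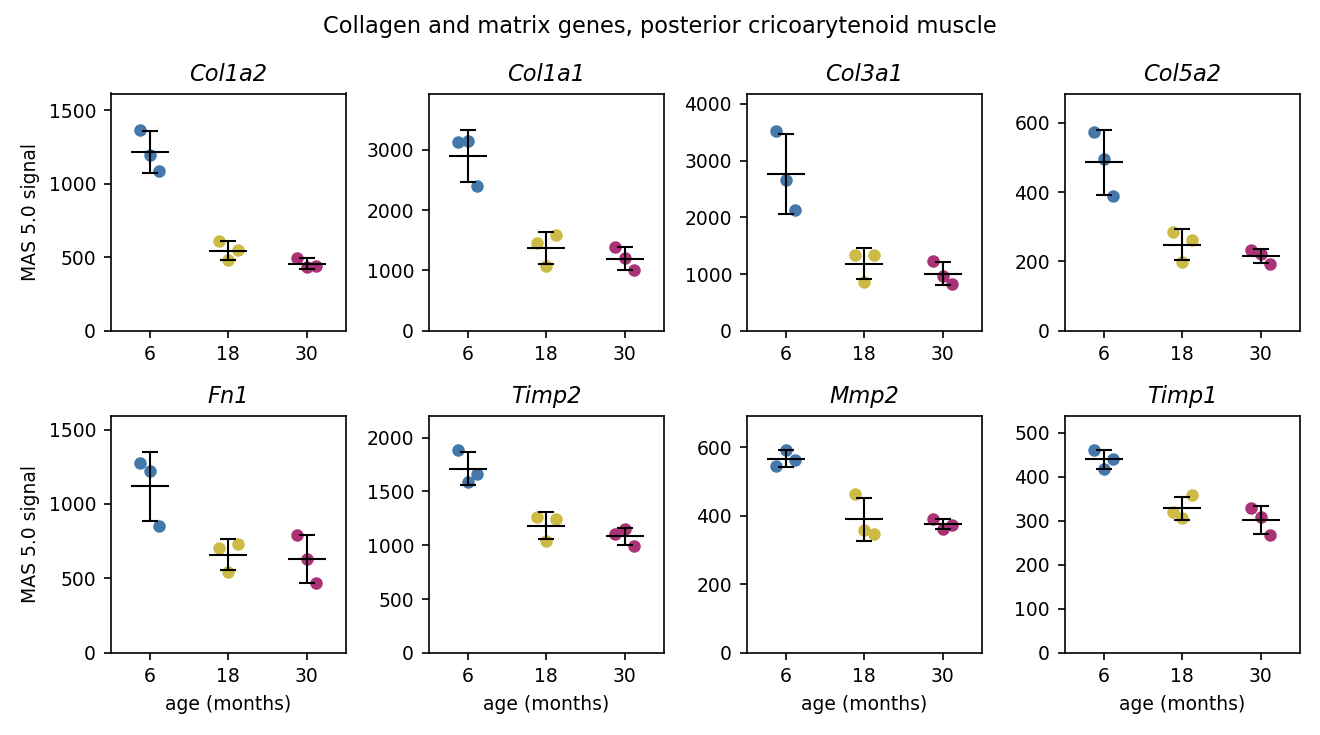
MAS 5.0 signal against age in months for 8 collagen and matrix genes, with 1 dot per array, the horizontal line at the mean and bars of 1 SD (n = 3 per age). For *Col1a2* the 6-month arrays lay between 1086 and 1365 and the 30-month arrays between 436 and 497; *Fn1*, *Timp2*, *Mmp2* and *Timp1* passed only adjusted over their lists alone.

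**Figure D3:**
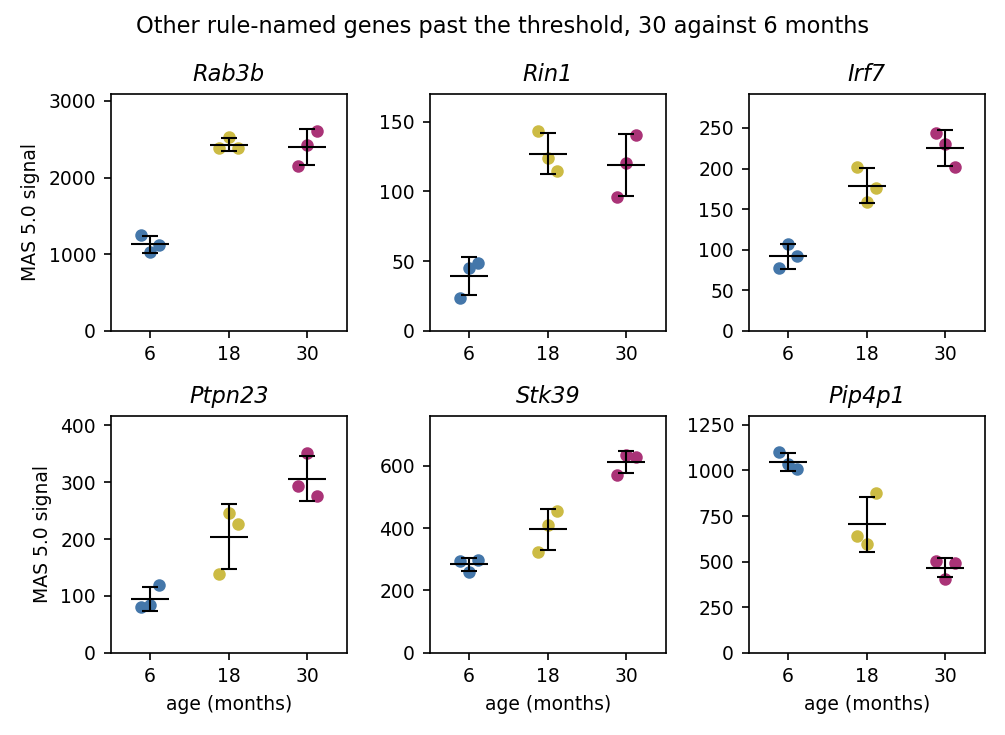
MAS 5.0 signal against age in months for the 6 genes outside the collagens that the naming rule gave past the threshold at 30 against 6 months, with 1 dot per array, the horizontal line at the mean and bars of 1 SD (n = 3 per age). *Rab3b* read 1128, 2431 and 2395 and *Stk39* 285, 396 and 611 at the 3 ages.

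At 30 months camera called 7 of 29 lists against 6 months, 6 higher and 1 lower. In the collagen and matrix list 19 of 21 genes were lower, with a median of -0.38 (adjusted p = 4.1e-07; adjusted p = 0.410 with an estimated correlation). The exceptions, looked up afterwards, were *Sparc* (0.13) and *Thbs4* (0.08); 3 other probe sets of *Sparc* read -0.14, -0.71 and -0.17. In this list 4 genes passed over all genes and 9 adjusted over the list alone, adding *Fn1* (-0.81), elastin (*Eln*, -0.52), lysyl oxidase (*Lox*, -0.50), lumican (*Lum*, -0.44) and *Lamc1* (-0.37). Other tested probe sets of *Fn1* read -0.41 and -0.23. The matrix remodelling list was not called by camera (median -0.24, adjusted p = 0.201), but fry passed it (adjusted p = 0.0449). In it 0 genes passed over all genes and 3 adjusted over the list alone. The protease inhibitor *Timp2* (-0.65, SE 0.13), the gelatinase *Mmp2* (-0.56) and *Timp1* (-0.50) were lower, as they had been at 18 months (-0.53, -0.52 and -0.39), where the camera adjusted p of the list was 0.135.

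The list of histocompatibility and antigen-presentation genes had a median of 0.16, with 10 of 15 genes higher (adjusted p = 0.00128; adjusted p = 0.410 with an estimated correlation). The immunoproteasome subunit *Psmb9* (0.60), the class II chaperone *RT1-DMb* (0.39) and the class I gene *RT1-CE16* (0.51) passed adjusted over the list alone, 3 genes, and 0 passed over all genes. At 18 months the same list was not called (adjusted p = 0.893). The ribosomal protein list had a median of only 0.07, with 31 of 36 genes higher (adjusted p = 0.00107; adjusted p = 0.410 with an estimated correlation), and the median was 0.03 after quantile normalization. Its genes *Rplp0* and *Rps29* had log2 changes of 0.25 and 0.18, and 0 genes passed either adjustment. At 18 months the ribosomal list had a median of 0.05 and was not called (adjusted p = 0.0682).

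The fast-fibre list at 30 months had a median of 0.18 (adjusted p = 1.2e-04; adjusted p = 0.411 with an estimated correlation), which was 0.01 after quantile normalization. The respiratory chain list had 22 of 28 genes higher and a median of 0.09 (adjusted p = 0.00979; adjusted p = 0.411 with an estimated correlation), and its median turned to -0.0164 after quantile normalization. *Cox8b* in that list had a log2 change of 0.31. The fatty acid oxidation list had a median of 0.10 with 19 of 26 genes higher (adjusted p = 0.00995; adjusted p = 0.411 with an estimated correlation), and the median was 0.03 after quantile normalization. In these 3 lists 0 genes passed either adjustment. The creatine list had a median of 0.18 (adjusted p = 0.0413; adjusted p = 0.410 with an estimated correlation). Its gene *Ckm* (0.42, SE 0.11) was the 1 gene to pass adjusted over the list alone, and 0 passed over all genes. The slow-fibre list was not called (median 0.10, adjusted p = 0.0628), which does not show that it differed from its state at 18 months. After quantile normalization camera called 2 lists instead of 7, the collagen and antigen-presentation lists.

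Leaving out 1 array removed some list calls at 30 months. The respiratory chain call was lost without replicate 3 of 6 months (adjusted p = 0.0557) or replicate 2 of 30 months (adjusted p = 0.0598). The fatty acid oxidation call was lost without replicate 3 of 30 months (adjusted p = 0.139), where the median was 0.02 against 0.10 in the main fit. The creatine call was lost without replicates 2 or 3 of 6 months (adjusted p = 0.0647 and 0.0871) or without replicates 1, 2 or 3 of 30 months (adjusted p = 0.0624, 0.0598 and 0.0577). In these fits the creatine median was 0.18 to 0.20, against 0.18 in the main fit. The creatine call also ended with replicate number as a block and with the upper 40% of probe sets, and its adjusted p ran from 0.00765 to 0.440 over all alternatives. The collagen, fast-fibre, ribosomal and antigen-presentation calls held in each of the 9 fits that left out 1 array. By fry 3 lists passed, the creatine list (adjusted p = 0.00781), the collagen list (adjusted p = 0.0284) and matrix remodelling.

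Between 18 and 30 months 1 of 5244 probe sets changed, X14254cds_at of *Cd74*, the invariant chain of class II antigen presentation, which was named after its values were seen. It rose 3.10-fold, from 39.5 ± 2.83 to 122 ± 15.6 (SD, n = 3; log2 change 1.11, SE 0.13, adjusted p = 0.0361), having read 55.1 ± 9.87 at 6 months. The *Cd74* probe set with the highest signal read 257 at 18 months and 494 at 30 months (log2 change 0.86, SE 0.24, adjusted p = 0.999). At an unadjusted p under 0.05 there were 168 probe sets, fewer than the 262.2 expected by chance, 77 higher and 91 lower. In 386 (7.36%) the ages did not overlap, against 10% by chance. The limma count was 0 without replicate 1 or 2 of 6 months, replicate 3 of 18 months or replicate 2 of 30 months, where 189, 155, 152 and 154 probe sets had an unadjusted p under 0.05. In 4 further fits, without replicate 1 or 2 of 18 months or replicate 1 or 3 of 30 months, the 1 call was another probe set, so the *Cd74* call held in 1 of the 9 fits, the one without replicate 3 of 6 months. The *Cd74* call also ended with replicate number as a block. Other settings that ended it were the larger pseudocount, the upper 40%, trend and robust settings, array weights and only the ages compared.

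Camera called 1 list between the later ages, antigen presentation, with 13 of 15 genes higher at 30 months and a median of 0.19 (adjusted p = 5.9e-06; adjusted p = 0.495 with an estimated correlation). In it 0 genes passed over all genes and 0 adjusted over the list alone. *Cd74* (0.86), *RT1-Da* (0.56), *Psmb9* (0.46) and *RT1-Bb* (0.36), picked after their values were seen, were among the higher genes. Without replicate 3 of 18 months or replicate 3 of 30 months camera called 2 lists. The collagen list was not called in this step (median -0.08, adjusted p = 0.920). The ribosomal list had a median of 0.04 (adjusted p = 0.128). Genes that led the ranking without passing included *Gdnf* (1.10), a neurotrophic factor that read 40.7 at 18 months and 118 at 30 months, and *Pde1b* (-0.84, adjusted p = 0.171), a phosphodiesterase that read 199 and 97.3. *Adar* (1.11), *Anp32a* (1.46), *Cyba* (1.04), *Igfbp5* (0.78), *Adprs* (0.75), *Neurod2* (0.76), *Il1rl2* (0.84), *Madd* (0.72), *Il2rb* (0.65) and *Camk2n1* (0.55) were on the higher side. *Nrn1* (-0.79), *Faim2* (-0.84), *Capn9* (-0.81), *Cd79b* (-0.64) and *Nab1* (-0.59) were on the lower side.

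In a test for any difference among the 3 ages, 14 probe sets in 10 named genes passed, and all 14 also passed in a pairwise comparison. At an unadjusted p under 0.05 there were 468. The 14 calls became 2, 0 and 3 without replicates 1, 2 and 3 of 6 months, 5 without replicate 3 of 18 months, and 5, 0 and 4 without replicates 1, 2 and 3 of 30 months. The fits with 0 had 373 and 343 at an unadjusted p under 0.05. Both comparisons with 6 months share the same 3 baseline arrays, which makes their changes correlate across probe sets whatever the biology. The observed correlation was 0.70, against 0.50 in 100 simulations with the shared arrays and no age effect, and 78.5% of probe sets had the same sign against 66.7%. The simulated noise was independent between probe sets and held no shift that depends on signal strength, which the arrays showed at both ages. The excess over the simulations therefore does not separate age from such a shift. The 4 probe sets called at 18 months were also called at 30 months, among them those of *Rab3b* and *Col1a2*. Since both comparisons use the same baseline arrays, this overlap is not independent evidence, and its size without an age effect was not computed.

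Genes of the neuromuscular junction and of denervation stayed without a call. Their list had a median of -0.01 at 18 months (adjusted p = 0.714) and at 30 months (adjusted p = 0.866), and the receptor subunits *Chrne* and *Chrna1* had log2 changes of -0.08 and -0.01 at 30 months. In the developmental muscle list the median at 30 months was 0.03 (adjusted p = 0.0838), and *H19* had a change of 0.39. The perinatal myosin *Myh8*, picked after its values were seen, read 618 ± 679 at 6 months and 99.6 ± 31.0 at 30 months (SD, n = 3), a spread at 6 months larger than its mean. Glycolysis (median 0.10, adjusted p = 0.0849; *Aldoa* 0.30) and the tricarboxylic acid cycle (0.01, adjusted p = 0.201; *Idh2* 0.20) were not called, nor were proteolysis (-0.02, adjusted p = 0.488; *Capns1* 0.04), antioxidant genes (0.03, adjusted p = 0.122; *Sod1* 0.22) and heat shock proteins (-0.05, adjusted p = 0.759; *Cryab* 0.39).

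Immune and other cell types had their own lists, and none of these was called at 30 months. Coverage was thin in some: 8 of 26 macrophage genes were tested, 10 of 31 lymphocyte and mast cell genes and 6 of 22 complement genes. For epithelium and glands it was 7 of 28 and for blood 5 of 12. The lack of a call therefore does not show that the share of these cells was unchanged. Medians were 0.04 for macrophages (adjusted p = 0.759; *Lyz2* 0.38), -0.18 for lymphocytes and mast cells (adjusted p = 0.488; *Tpsb2* -0.47) and -0.06 for complement (adjusted p = 0.566; *Cfd* -0.05). Blood genes had a median of 0.09 (adjusted p = 0.132), with *Hbb* at 0.34. Schwann cell and nerve genes (-0.04, adjusted p = 0.866; *Pmp22* -0.30), adipocyte genes (-0.16, adjusted p = 0.391; *Lpl* 0.04) and endothelial and smooth muscle genes (-0.08, adjusted p = 0.759; *Acta2* 0.02) were not called. The same held for epithelium and glands (-0.25, adjusted p = 0.325; *Sprr1a* -0.28) and for thyroid and parathyroid (-0.07, adjusted p = 0.759; *Tshr* 0.34). At 18 months *Dio1* (-0.57) and *Pax8* (-0.64) of the thyroid list, 2 genes, passed adjusted over the list alone and 0 over all genes, and the list itself was not called (adjusted p = 0.488).

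The growth axis, stress and cycle lists were also not called. The insulin and growth factor list had a median of -0.11 at 30 months (adjusted p = 0.809; *Igf2* 0.37), and at 18 months *Inhba* was the 1 gene in it to pass adjusted over the list alone. Immediate early genes had a median of -0.07 (adjusted p = 0.759; *Nr4a1* 0.18) and the cell cycle list -0.10 (adjusted p = 0.759; *Ccnd3* -0.07). The clock list (adjusted p = 0.570; *Bhlhe41* 0.18) held 4 genes that were higher and 5 that were lower. In a few uncalled lists, among them heat shock, proteolysis and insulin and growth factor genes at 30 months, the median was negative while camera ranked the list higher. At 18 months the lowest adjusted p among the lists without a call at either age was 0.0985, of developmental muscle, and between the later ages no list but antigen presentation was called. Of the 15 cartilage genes 8 were on the array and 2 passed the signal filter, too few for a list test. Of these, *Col10a1* read 197 at 6 months and 125 at 30 months.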

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

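The tests on random lists matched on signal at 18 months were chosen after the results were seen. With 3 arrays per age no single array could be called far from its group by a rule.

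*Cd74*, by probe set X14254cds_at, differed between the ages above 6 months: its change against 6 months was 1.11 higher on the log2 scale at 30 months than at 18 months (SE 0.13, adjusted p = 0.0361). The mean signals were 55.1, 39.5 and 122 at the 3 ages. The mean log2 of 6.62 lay just above the filter's cutoff of 6.60. The *Cd74* probe set with the highest signal had a change of 0.86 between the same ages, and the others 0.49 and 1.18. The 10 splits of these 6 arrays were too few for a share under 0.05. The real split gave 1 call and the highest other also 1, so 2 splits gave as many. The call held in 1 of the 9 fits that left out 1 array, the one without replicate 3 of 6 months.

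Collagen and matrix genes were lower at 30 months than at 6 months, by a median of -0.38. If less connective tissue of any kind were the whole cause, fibroblast markers outside the matrix lists would fall about as much. Of these markers 18 of 36 were measured, with a median of -0.14 (95% interval -0.34 to 0.03, with 12 of the 18 lower), above the list by 0.03 to 0.51. Both intervals resample genes measured in the same pools, so they do not hold the spread between pools. They cannot decide whether less connective tissue is the whole cause. The abundant *Lgals1* (mean signals 7897 and 8232), *Mgp* (4138 and 4402) and *Vim* (1906 and 1913) were not lower, but *Igfbp6* (-0.53), *S100a10* (-0.47), *S100a4* (-0.47), *Rcn2* (-0.42) and *Anxa1* (-0.31) were on the lower side, 3 of the markers sit in another list, and at 18 months the markers had a median of -0.22 against -0.31 for the list. One outlying array is argued against, since the smallest median in fits without 1 array was -0.34, and the scaling of the arrays is argued against as the whole cause, since the median was -0.26 after quantile normalization. A loss of connective tissue, whole or partial, stays open, and so does age itself as an untested explanation.

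The fast-fibre, respiratory chain, creatine, fatty acid and ribosome lists were called higher at 30 months than at 6 months by camera at its preset correlation, 0 of them with an estimated correlation, and the slow-fibre list, tested with them, was not called (adjusted p = 0.0628). A shift that depends on signal intensity fits: 1 of the 6 lists lay above the central 95% of random lists matched on signal, the creatine list at percentile 98.3. The random lists were drawn from all genes of like signal, those of the tested lists included. A real rise of many strongly expressed genes would raise the random lists too, so this result cannot tell it from the shift. The scaling of the arrays fits too, since 2 of the 6 lists kept most of their median after quantile normalization. That normalization removes a rise shared by strong signals whether it is real or not, so this result cannot tell them apart either. At 18 months 0 of the 4 fast-fibre and energy lists lay above that range, as such a shift would leave them. The slow-fibre list lay at 99.95. The draws ignore the correlation between genes of a list, estimated at 0.28 for slow fibre, so this percentile overstates the evidence against the shift. A rise of slow-fibre genes with age may remain at 18 months, though its call ended under quantile normalization with a median of 0.19 (adjusted p = 0.237, and 0.000573 to 0.432 over its alternatives). For all these lists the shift and age stay open.

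Thyroglobulin (*Tg*) was high in 2 pools. Probe set X02318_at read 628 in replicate 3 of 18 months and 555 in replicate 3 of 30 months, against 30.2 to 109 in the other 7 arrays. Thyroid tissue in these pools is a candidate explanation, but 0 of 10 other thyroid genes, on 16 probe sets, had their highest values in both of these arrays, where chance gives 2.78% per probe set. The values of *Foxe1* in these arrays (mean 343) lay within the range of the other 7 (259 to 386), as did those of *Tshr* (256, probe set D38036_at, 151 to 300.3) and *Pax8* (169, 98.5 to 269), and *Dio1* (probe set rc_AI639418_at) had a mean of 110 against 118. Signals of that size in every pool would hide a small share of thyroid tissue, whose level of these genes was not measured, so thyroid tissue and a cause in the animals both stay open.

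For the counts of probe sets past the threshold, the splits of 6 arrays into 3 and 3 were too few for a share under 0.05. The real split gave 4 calls at 18 months against at most 1 in the others, and 17 at 30 months against 0, so in each case 1 split, the real one, reached its count. For the lists the real split gave 6 at 18 months against at most 5, and 7 at 30 months against at most 6, again 1 split each. Between 18 and 30 months it gave 1 list against up to 6, and 6 splits gave as many. For any age difference 2 of 100 splits drawn of 280 gave 14 calls or more, with 14 the highest other, which excludes chance at 0.05 only for splits that ignore replicate numbers. Those numbers paired the arrays in part, the count with the replicate block was 4, and splits within replicate numbers were not run. The other split that reached 14 keeps the 3 arrays of 6 months together.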

How the results depend on the processing

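The fits without both thyroglobulin-rich arrays and without both arrays of lowest weight were chosen after the data were seen. Of 261 alternatives of the 12 results of named genes past the threshold, 154 kept the call, 107 kept the direction without passing, and 0 turned. These genes were chosen for values without overlap between ages, so leaving out 1 array could not turn their direction. The threshold of 0.10 kept each call by construction. Of 4932 alternatives of uncalled named results, 13 passed and 218 had the other sign without passing. *Col1a2* at 30 months stayed between -1.42 and -1.20 (adjusted p 0.00144 to 0.0953), and *Rab3b* at 18 months between 1.02 and 1.18 (adjusted p 0.00113 to 0.118). *Rin1* at 30 months ran from 0.56 to 1.46 and lost its call in 16 of 21 alternatives.

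Leaving out 1 array gave 0 to 5 calls at 18 months (limma), 0 to 20 at 30 months, 0 to 1 between the later ages and 0 to 11 for any age difference. Lists called ran from 2 to 7, 5 to 10 and 1 to 2. The lows of 0 came without replicate 2 of 6 months, where 407, 580.0, 155 and 373 probe sets had an unadjusted p under 0.05, among other fits. Fewer arrays lower the power by construction.

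A pseudocount of 8 gave 6 probe sets for any age difference. The larger pseudocount gave 8 at 18 months and 0 between the later ages (161 at unadjusted p under 0.05). Without a filter there were 4 between the later ages and 6 for any difference, and with the upper 40% 0 between them (92 unadjusted). Quantile normalization gave 9 for any difference and 1 and 2 lists at 18 and 30 months, and median centring 9 for any difference. At 18 months both scalings gave 4 higher and 2 lower instead of 2 and 2, and at 30 months quantile normalization gave 9 and 6 instead of 8 and 9. Trend and robust settings gave 8 at 18 months and 0 between the later ages (151 unadjusted), and array weights 0 (195 unadjusted). With only the ages compared, 18 months gave 0 (378 unadjusted) and the later ages 0 (168 unadjusted). The cause was not tested.

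Without both thyroglobulin-rich arrays limma gave 0 for all 3 comparisons and any difference (416, 572, 151 and 421 unadjusted), with 3 lists at 18 months and 2 between the later ages. Without both arrays of lowest weight it gave 1 at 18 months, 7 at 30 months and 1 for any difference. The fold rule gave 75, 117 and 33 probe sets. With an estimated correlation camera called 0, 0 and 0 lists (2, 3 and 2 unadjusted), and fry 1, 3 and 0 (1 unadjusted).

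The respiratory chain list reversed under quantile normalization, with a median of 0.0017 at 18 months and -0.0164 at 30 months; the normalization removes the shift between strong and weak signals by construction.

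Replicate numbers paired arrays in part: 8 of 9 arrays correlated best with their own number after the age means were removed, and 4 of 9 pairs exceeded 0.1 (-0.0209 to 0.261). With the replicate block there were 11 calls at 30 months, 0 between the later ages (220.0 unadjusted) and 4 for any difference; the 11 were all among the 17, and the representative probe sets of *Col1a1*, *Col5a2* and *Rin1* were past the threshold no longer. The block gave 6 lists at 30 months, without the creatine list.

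Signals near the floor limit what can be tested: 17.7% to 23.2% of probe sets read under 20. Splitting the baseline arrays between both comparisons was not run, since there are 3.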

Other observations

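The percentiles at 18 months and between the later ages were read after the results were seen, and the genes named here were chosen after their values were seen. Some genes below the signal filter passed the limma threshold when no filter was applied. *Igfbp3*, which encodes a carrier of insulin-like growth factors, read 59.5 ± 5.22 at 6 months, 12.4 ± 3.76 at 18 months and 14.7 ± 2.31 at 30 months (SD, n = 3). Its later values are near the floor, so the size of its log2 change is set largely by the pseudocount and is not given. *Otc*, of the urea cycle, read 54.1, 11.5 and 43.2, and the aldehyde dehydrogenase gene *Aldh3a2* read 31.2, 30.2 and 80.4. Between 18 and 30 months *Hes5*, a Notch target, read 108 and 34.8, and *Slc40a1*, which encodes the iron exporter ferroportin, read 13.1 and 70.6. Also past the threshold were *Vom2r46* (82.1, 11.4 and 50.1 at the 3 ages), *Olr1191* (79.1, 62.8 and 21.7) and *Npy5r* (21.7, 4.57 and 2.27). The lowest values of *Otc*, *Slc40a1*, *Vom2r46* and *Npy5r* are near the floor as well, so background may account for such calls.

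In random lists matched on signal, the median of the antigen-presentation list lay at percentile 88.7 at 18 months, 99.9 at 30 months and 99.99 between the later ages. Between the later ages the ribosome list lay at 99.91 (median 0.04) and the slow-fibre list at 0.56 (median -0.10), and camera called neither (adjusted p = 0.128 and 0.920). The median of the collagen list lay at percentile 0 against 6 months at both ages. The random lists ignore the correlation between genes of a list, so these percentiles are not p-values.

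The hexokinase 3' to 5' ratio ran from 0.797 to 4.05, with the highest value in replicate 1 of 18 months. Estimated array weights ran from 0.570 in that array and 0.581 in replicate 1 of 6 months to 1.53 in replicate 2 of 6 months.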
